A study of Mus musculus with 12 samples.

How the data were processed

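RNA sequencing was carried out on 12 mouse melanoma tumors, 6 with an intact Arf6 gene and 6 without it, on the Braf and Cdkn2a mutant background that all tumors share. Per the labels' protocols, RNA was isolated with a Direct-zol kit and libraries were prepared with the TruSeq Stranded mRNA kit, which selects polyadenylated RNA and keeps the strand of the transcript. The submitters' processing notes name the aligner STAR 2.7.3a, the read counter featureCounts 1.6.3 and DESeq2 1.26.0, and the mouse build GRCm38 (mm10). The strand setting of the counter, its handling of reads that map to several places and the annotation release are not given in the sources used here. The deposited table holds raw counts of reads per gene, whole numbers without normalization, for 55487 Ensembl gene identifiers, of which 22114 had no read in any library.

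Groups were taken from the genotype in the sample labels and columns were matched to samples by the library name in the titles. The design text calls the tumors of the groups matched, and no label ties a particular tumor of one genotype to a tumor of the other, so no block was fitted. Gene symbols and coordinates came from GENCODE release M21 of GRCm38, which held 55141 of the identifiers. Identifiers without a symbol took at most 0.0394% of the counts of a library. Totals per library lay between 21007954 and 45688253 counts. No pair among the 66 pairs of libraries agreed within sampling noise: the chi-square per degree of freedom of the closest pair, Arf6-null replicates 1 and 5, was 93.1. The title of each sample carries a different tumor number, and the labels do not say whether the tumors came from separate animals, so p-values measure the spread between these samples.

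Genes with too few counts were removed with filterByExpr at its default minimum of 10 counts, which left 16225 genes holding 99.9% of all counts. Library sizes were scaled by the trimmed mean of M values. Genotypes were compared with the quasi-likelihood F test of edgeR 4.0.16 with robust dispersion estimates in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes with a threshold of 0.05. Log2 fold changes are Arf6-null over wild type, and standard errors were derived from the F statistic. Normalized levels are CPM (counts scaled to a common library total) computed from the deposited counts with the scaled library sizes, and log2 CPM values used a prior count of 2. Intervals cover counting error only.

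A total of 37 gene lists, covering pathways, cell types and RNA handling, was written down before the data were examined, as were the tests, the alternatives in the main set and the rule for naming genes. Of these, 36 were tested with fry of limma 3.58.1 on voom values, two-sided, with adjustment over the lists. The mean of a list is taken over the voom log2 fold changes of its members, unless edgeR is named. The list of 4 Y-linked genes served as a covariate. The score of a list in a library is the mean log2 CPM of its tested members. Named genes were Arf6, Braf, Cdkn2a, Ifngr1 and Ifngr2, then up to 12 genes per direction with the largest fold change among those past the threshold, with a protein name (no Gm number or Rik, ribosomal Rps or Rpl, microRNA, immunoglobulin or T cell receptor segment, or pseudogene symbol), with at least 1 CPM in the higher group and past the threshold in each of the 12 fits that leave out 1 library, filled up to 4 by smallest p, and then the members of each list with the smallest p, up to 4 for a list past the threshold and up to 2 for any other.

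Alternatives fixed in advance were median-of-ratios and upper-quartile scaling, the Wald test of DESeq2 1.42.0, limma-voom with sample quality weights, no filter, a filter of 10 CPM in 6 libraries, Y-linked expression as a covariate, each library left out in turn, a threshold of 0.1, a further limit of 2-fold, and for lists camera with a preset correlation of 0.01 or an estimated one and an exact permutation test over 924 splits. Added after seeing the data were counts thinned to 21007954 per library, a fit without the 3 wild-type libraries with the highest skeletal muscle score, and that score as a covariate. The functions were tested on simulated counts for the Arf6-null against wild-type comparison, with 200 of 16048 genes changed. The test called 49% of the 2-fold and 75% of the 4-fold changes, with 5 false calls among 129, and 0 calls when no gene was changed. A list shifted 1.5-fold was called, and no other list was. The simulated genes varied independently, and the simulated samples had no structure beside the genotype. In the data the estimated correlation between members was 0.597 for hypoxia and glycolysis genes and 0.878 for skeletal muscle markers. The simulation therefore does not show the power or the false calls for such lists or samples.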

Results

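Bulk RNA-seq profiles were obtained from 12 mouse melanoma tumors that carry the BrafCA allele together with floxed Cdkn2a. In 6 tumors Arf6 was intact (wild type) and in 6 it was removed (Arf6-null). Arf6 encodes a small GTPase that regulates traffic between the plasma membrane and endosomes. The comparison asks how loss of Arf6 in the tumor changes gene expression, including that of immune and interferon genes. Read totals ran from 22211738 to 30326419 counts in the wild-type libraries and from 21007954 to 45688253 in the Arf6-null libraries, which were deeper on average (exact permutation p = 0.0455, two-sided, n = 6 each). The genotypes were also separate in library numbering, with wild-type libraries numbered 1 to 6 and Arf6-null libraries 19 to 24. A difference between preparation rounds, if there was any, would fall along the genotypes. Tumor numbers in the titles ran from 5526 to 7657 in wild type, except for 20681 in replicate 5, and from 19836 to 20570 in Arf6-null. Apart from that replicate they also follow the genotypes. Sex was not balanced: Xist exceeded 100 CPM in wild-type replicates 3, 5 and 6 and in Arf6-null replicate 6, and the sum of 4 Y-linked genes exceeded 10 CPM in 3 wild-type and 5 Arf6-null libraries. The first principal component held 30.7% of the variance and differed on average between genotypes (exact permutation p = 0.00433). The genotypes overlapped on it, with wild-type replicate 2 at 10.5 and Arf6-null replicate 6 at -9.18. The other wild-type libraries lay from -79.5 to -20.3 and the other Arf6-null libraries from 40.4 to 88.4.

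Arf6 itself was lower in every Arf6-null library. Its level was 111 ± 24.9 CPM in wild-type tumors and 18.3 ± 3.73 CPM in Arf6-null tumors (SD, n = 6 each), a 6.07-fold difference with no overlap between the ranges of 84.2 to 147 CPM and 12.2 to 22.5 CPM. The log2 fold change was -2.60 (SE 0.18, edgeR adjusted p = 0.000101). The gene lies on chromosome 12 at 69372150 to 69373783 of GRCm38. Gm9887, which overlaps it on the other strand, had a log2 fold change of -3.10 (SE 0.41, edgeR adjusted p = 0.0073), and its reads cannot be told from those of Arf6 without the strand setting. Neither of the other engineered genes passed the test: Braf was at 34.9 ± 5.22 and 39.6 ± 8.48 CPM and Cdkn2a at 19.5 ± 4.74 and 17.1 ± 4.10 CPM in wild-type and Arf6-null tumors (edgeR adjusted p = 0.503 and 0.592). The counts cover whole genes and do not show which exons remained.

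Among the genes taken by the naming rule, the largest increases were in Trim12a, Ifi44l, H2-Eb1, Trim5 and H2-T22. H2-Eb1, which encodes an MHC class II beta chain, rose from 12.03 ± 10.3 to 375 ± 150 CPM (log2 fold change 4.96, SE 0.75, edgeR adjusted p = 0.0183). H2-T22, a non-classical MHC class I gene, rose from 5.95 ± 3.75 to 79.8 ± 15.9 CPM (log2 fold change 3.74, SE 0.36, edgeR adjusted p = 0.000612). The interferon-inducible gene Ifi44l was at 0.0595 ± 0.0388 CPM in wild-type and 8.87 ± 6.07 CPM in Arf6-null tumors, 10 against 1960 counts. Wild-type replicates 5 and 6 had type I interferon target scores of 5.40 and 5.29, within the Arf6-null range of 4.50 to 5.50. Their Ifi44l was at 0.0746 and 0.0347 CPM, so its difference between genotypes did not follow this score. Trim12a and Trim5 are neighbors on chromosome 7 and belong to a family of antiviral factors. Trim12a had 2 counts over the wild-type and 1544 over the Arf6-null libraries, a ratio of 613 (95% counting interval 169 to 5065), and Trim5 rose from 0.164 ± 0.109 to 2.42 ± 0.916 CPM. These genes have close relatives in the genome, so counts can be split or moved between copies. Inherited differences, taken up below, were not excluded for Trim12a, Ifi44l, H2-Eb1, Trim5 and H2-T22. The other named genes that rose were Ankrd66, Vcpkmt, mt-Nd6, Nudt9, Dnttip1 and Galk1. Vcpkmt lies close to Arf6, at 69577628 to 69583028 of chromosome 12, and called genes near Arf6 are taken up below. Galk1, the first enzyme of galactose breakdown, rose from 55.9 ± 2.65 to 85.4 ± 10.97 CPM, and Nudt9, an ADP-ribose hydrolase, from 105 ± 15.1 to 190 ± 21.5 CPM. mt-Nd6, a complex I subunit encoded on the light strand of mitochondrial DNA, rose from 9.04 ± 1.37 to 18.1 ± 2.64 CPM and overlaps mt-Nd5 on the other strand.

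**Figure D1:**
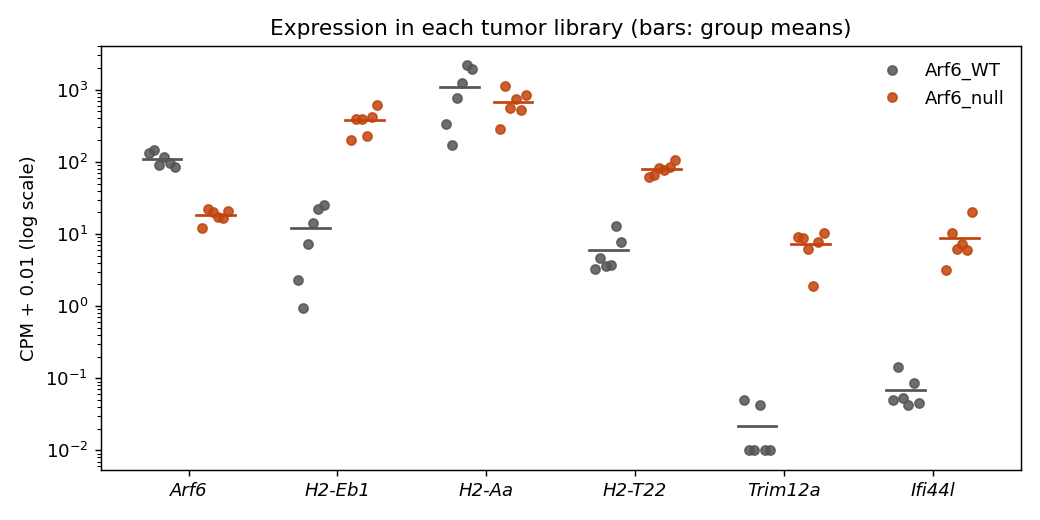
Normalized level (CPM, log scale with a small offset) of 6 genes in each of the 12 tumor libraries, with wild type in gray, Arf6-null in orange and bars at the group means. The ranges of H2-Eb1 did not overlap (0.926 to 25.1 CPM in wild type and 199 to 616 CPM in Arf6-null), whereas those of H2-Aa did.

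Of the named genes fewer fell than rose. Ptp4a3, a phosphatase of the PRL family, fell from 65.7 ± 9.06 to 26.4 ± 7.68 CPM (log2 fold change -1.31, SE 0.19, edgeR adjusted p = 0.0137). Cda, which encodes cytidine deaminase, fell from 4.30 ± 4.15 to 0.123 ± 0.0835 CPM (log2 fold change -5.02, SE 0.75). Galnt5, a glycosyltransferase that starts O-linked glycans, fell from 1.45 ± 0.831 to 0.182 ± 0.0831 CPM and was called in 11 of the 12 fits. Across all 16225 tested genes, 95 were higher and 91 lower in Arf6-null tumors at an edgeR adjusted p under 0.05, 186 in all, and 36 and 70 of them differed by at least 2-fold. At an unadjusted p under 0.05 the counts were 1785 and 2014. With Y-linked expression as a covariate 14 and 17 genes were called and 157 of the 186 calls were lost. DESeq2, run on 33373 genes without the filterByExpr step, called 970 and 1247. With upper-quartile scaling 41.4% of the calls were higher, against 51.1% here. The number called depended on single libraries. It was 27, 766, 37, 35, 537 and 27 without wild-type replicate 1, 2, 3, 4, 5 and 6, and 25, 35, 122, 69, 154 and 672 without Arf6-null replicate 1, 2, 3, 4, 5 and 6. Only 19 of the 186 genes were called in all 12 of these fits.

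**Figure D2:**
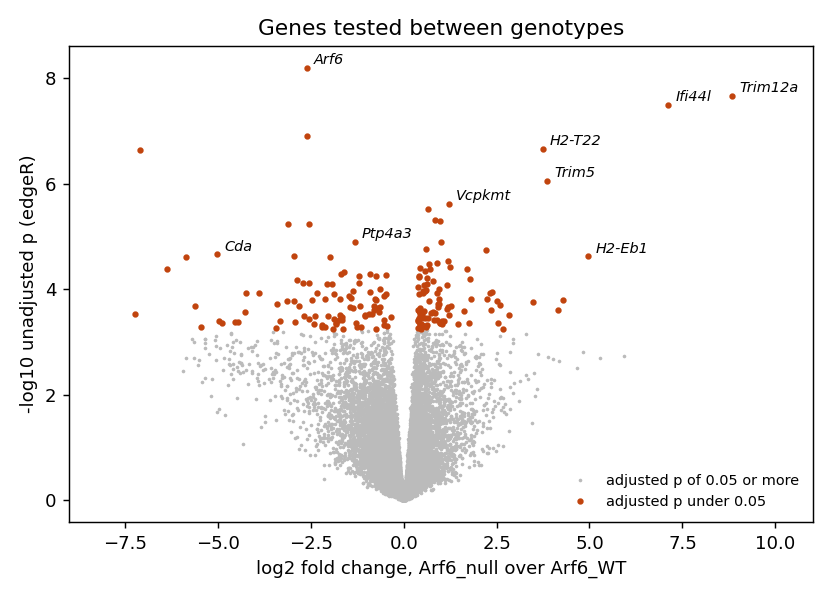
Log2 fold change (Arf6-null over wild type, horizontal) against -log10 of the unadjusted edgeR p (vertical) for 16225 genes, with the 186 genes at an adjusted p under 0.05 in orange. Arf6 has the smallest p of all tested genes.

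No list of ARF pathway genes passed the directional test. List means here and below are means of voom log2 fold changes, the values that fry tests, which average log levels over libraries, while fold changes of single genes are from edgeR. Permutation p of list scores are unadjusted unless stated, and none passed after adjustment. Among 26 tested ARF6 exchange factors and GTPase-activating proteins, Cyth2, an exchange factor, rose from 95.9 ± 7.71 to 141 ± 18.3 CPM and Agap2, a GTPase-activating protein, fell from 9.95 ± 2.66 to 3.08 ± 1.13 CPM (edgeR adjusted p = 0.0267 and 0.0239). They were called in 6 and 9 of the 12 leave-one-out fits, and 1 higher and 4 lower members passed when adjusted over the list alone. The mean log2 fold change of the list was -0.28 (fry adjusted p = 0.187, exact permutation p of the score = 0.00649). For 17 other ARF GTPases it was 0.22 (fry adjusted p = 0.187, exact permutation p of the score = 0.0152), with no member called over all genes and 2 higher and 2 lower members adjusted over the list alone. Arf5 was at 100.5 ± 7.69 and 129.9 ± 15.5 CPM in wild-type and Arf6-null tumors, and Arl5a at 87.5 ± 23.6 and 57.6 ± 6.55 CPM. Endocytic recycling genes had a mean of 0.09 over 34 members (fry adjusted p = 0.187), and lysosome genes one of 0.15 over 28 (fry adjusted p = 0.342), with no member called in either. Ehd2 was at 306 ± 31.8 and 401 ± 40.8 CPM, and Ctsb at 2328 ± 622 and 3471 ± 273 CPM.

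In the antigen presentation lists only single members changed, each of them in the MHC region of chromosome 17 (33 to 37 Mb). Inherited differences in this region, taken up below, were not excluded, so these calls cannot be credited to Arf6 loss alone. In the MHC class I list 2 of 21 tested members rose and 19 did not pass. These were H2-T22 and H2-T23, the latter from 32.7 ± 23.7 to 154.1 ± 39.0 CPM (edgeR adjusted p = 0.0318, called in 5 of the 12 leave-one-out fits). The mean log2 fold change of the list was 0.84 (fry adjusted p = 0.187, exact permutation p of the score = 0.0541). In the MHC class II list H2-Eb1 rose and 10 of 11 members did not pass. H2-Aa was at 1104 ± 830 CPM in wild type and 679 ± 288 CPM in Arf6-null tumors (edgeR adjusted p = 0.47), and H2-Ob at 4.54 ± 2.77 and 1.51 ± 0.473 CPM. The voom mean of this list was 0.28 and its voom median -0.12, and the edgeR values of the members had a mean of -0.077, so the direction of the list is not settled (fry adjusted p = 0.781). The interferon-gamma receptor genes Ifngr1 and Ifngr2 were at 272 ± 123 and 130.1 ± 37.4 CPM in wild-type tumors and at 170.1 ± 58.1 and 118 ± 25.5 CPM in Arf6-null tumors (edgeR adjusted p = 0.262 and 0.717). No member passed among 16 genes of interferon-gamma signalling (mean 0.21), 29 interferon-gamma targets (mean 1.03) or 26 type I interferon targets (mean 0.91), with fry adjusted p of 0.498, 0.329 and 0.187. By edgeR the means of the targets were lower, 0.55 and 0.57, and 26 of 29 and 24 of 26 had a positive edgeR log2 fold change. Bst2 was at 59.0 ± 34.2 and 107 ± 30.8 CPM, Usp18 at 16.1 ± 12.8 and 35.1 ± 7.92 CPM, and Upp1 at 207 ± 133 and 431 ± 105 CPM.

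Hypoxia and glycolysis genes had the smallest directional fry p of the lists, which did not pass after adjustment. All 26 tested members had a positive log2 fold change on both scales, 2 rose over all genes and 18 passed when adjusted over the list alone. Pfkl, a phosphofructokinase, rose from 129 ± 53.1 to 359 ± 109.8 CPM and Tpi1, triosephosphate isomerase, from 488 ± 109 to 993 ± 267 CPM (edgeR adjusted p = 0.0448 and 0.0435), each called in 3 of the 12 leave-one-out fits. The mean log2 fold change was 1.03 (fry adjusted p = 0.187, exact permutation p of the score = 0.0130). The list passed without Arf6-null replicate 6, with a mean of 1.22 (fry adjusted p = 0.0328; range over 21 alternatives 0.0328 to 0.391). Over all 12 libraries camera gave an adjusted p = 0.583 with an estimated correlation for this list. The score of the list in Arf6-null replicate 6, at 5.93, lay within the wild-type range of 5.25 to 6.55. Scores of skeletal muscle and of fibroblast and collagen matrix genes were lower in Arf6-null tumors, by -3.41 and -0.90 (exact permutation p = 0.0195 and 0.0303, adjusted 0.14 and 0.156).

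Immune cell markers did not separate the genotypes as lists. Mean log2 fold changes were -0.28 for 20 T cell markers, -0.02 for 18 cytotoxic lymphocyte markers, 0.31 for 22 regulatory T cell and checkpoint genes, -0.59 for 8 B and plasma cell markers and -0.23 for 22 macrophage and monocyte markers, with fry adjusted p of 0.795, 0.851, 0.64, 0.342 and 0.565. The sign of the T cell and cytotoxic means turned under some alternatives. Tcf7 was at 19.5 ± 4.18 and 30.7 ± 9.13 CPM, Gzma at 16.2 ± 17.2 and 5.11 ± 3.20 CPM, and the checkpoint receptor gene Tigit at 5.69 ± 4.19 and 15.1 ± 8.69 CPM. Dendritic cell markers had a mean of -1.18 over 15 members (fry adjusted p = 0.187), and Cd209a, a lectin of monocyte-derived cells, fell from 2.73 ± 2.07 to 0.142 ± 0.106 CPM (edgeR adjusted p = 0.0292, called in 5 of the 12 leave-one-out fits). Mast cell markers had a mean of -2.29 over 11 members (fry adjusted p = 0.187, exact permutation p of the score = 0.0130). No member passed over all genes and 9 did adjusted over the list alone. The protease gene Tpsb2 was at 91.8 ± 74.8 CPM in wild-type and 14.1 ± 9.47 CPM in Arf6-null tumors. Neutrophil and myeloid suppressor genes had a voom mean of 0.93 and an edgeR mean of 0.24 over 18 members (fry adjusted p = 0.342). By edgeR 9 members were positive and 9 negative, with Il1b at 22.02 ± 18.3 and 52.3 ± 26.4 CPM.

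Markers of muscle, connective tissue, vessels and nerve had negative mean log2 fold changes, and no such list passed. Skeletal muscle markers had a voom mean of -3.38 and an edgeR mean of -4.59, all 19 members negative on both scales (fry adjusted p = 0.187, exact permutation p of the score = 0.0195). Pvalb fell from 25.7 ± 37.3 to 0.17 ± 0.152 CPM (edgeR adjusted p = 0.0392, called in 3 of the 12 leave-one-out fits), and all 19 members passed when adjusted over the list alone. The signal came from few libraries: the muscle score was 6.87, 6.05 and 6.80 in wild-type replicates 3, 4 and 5 and at most 3.38 elsewhere. Without those 3 libraries 35 genes were called, and 20 with the muscle score as a covariate. Means were -0.91 for 23 fibroblast and collagen matrix genes, -0.71 for 16 endothelial markers, -0.67 for 13 Schwann cell and myelin markers, -1.50 for 8 adipocyte markers and -0.47 for 20 TGF-beta targets. Their fry adjusted p was 0.187 for all but the adipocyte list, where it was 0.395. No member of these lists passed over all genes. Postn was at 1874 ± 1387 CPM in wild-type and 356 ± 370.2 CPM in Arf6-null tumors, and Tie1 at 30.1 ± 12.2 and 12.4 ± 7.10 CPM.

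Melanocyte genes ranged from undetected to moderate levels in both genotypes. Of the list, 10 of 22 pigment and melanocyte lineage genes had enough counts to test, with a mean of -0.30 (fry adjusted p = 0.342). Mlana had 0 counts in every library. Sox10 had 0 to 33 counts per library, Tyr 0 to 2 and Dct 0 to 1, so these lineage genes were near or at the floor. Gpnmb was at 39.0 ± 38.9 and 44.3 ± 50.6 CPM and Mitf, the lineage transcription factor, at 18.6 ± 6.74 and 18.2 ± 8.78 CPM. Kit was at 15.4 ± 5.27 and 5.28 ± 2.64 CPM (edgeR adjusted p = 0.0629). Dedifferentiated and neural crest melanoma genes had a mean of 0.05 and a median of -0.002 over 20 members on the voom scale, which differ in sign (fry adjusted p = 0.395). Fosl1 was at 59.3 ± 26.9 and 111.1 ± 31.7 CPM. The remaining lists gave means of 0.07 for MAPK output, -0.06 for proliferation, -0.18 for Wnt targets, 0.22 for p53 targets, 0.50 for inflammatory cytokines and 0.28 for the integrated stress response, and of 0.36 for immediate early and heat shock genes, 0.73 for keratinocyte markers, 0.79 (by edgeR 1.06) for red blood cell transcripts and 0.28 for mitochondrially encoded transcripts. Their fry adjusted p was 0.66, 0.879, 0.749, 0.379, 0.342, 0.187, 0.342, 0.342, 0.498 and 0.187. None of the 36 lists passed with directional fry, 8 had an unadjusted p under 0.05, 14 passed with camera at a preset correlation, and none passed with an estimated correlation (smallest adjusted p = 0.583 with an estimated correlation) or with the exact permutation test. The mixed test of fry, which asks whether members change in either direction, passed for 15 lists. Its adjusted p was 9.6e-05 for ARF6 exchange factors and GTPase-activating proteins and 0.00443 for other ARF GTPases, for endocytic recycling and for MHC class I. The mixed test does not compare a list with the other genes. Of all 16225 tested genes, 3799 had an unadjusted edgeR p under 0.05, so a pass does not set a list apart from them.

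**Figure D3:**
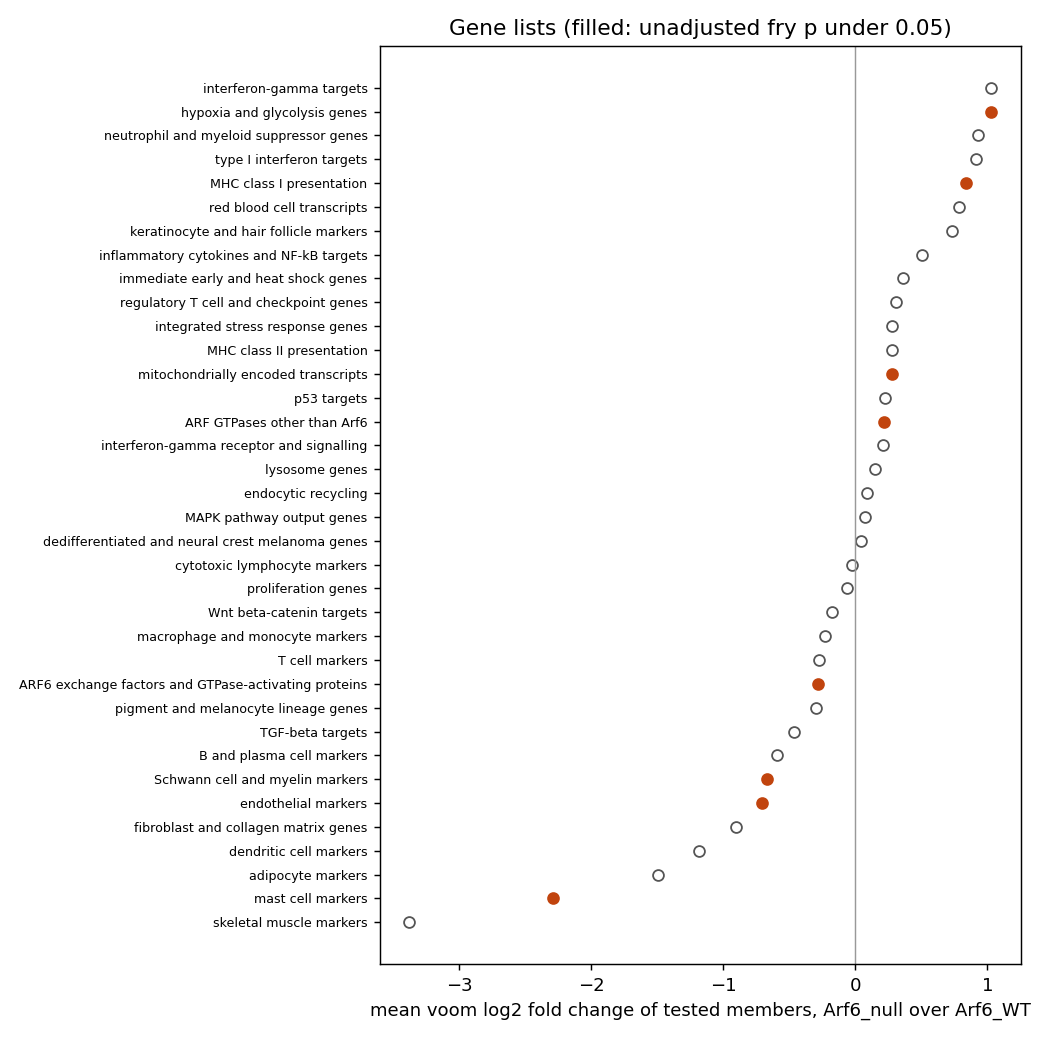
Mean voom log2 fold change (Arf6-null over wild type, horizontal) of the tested members of each of the 36 gene lists (rows), with filled points for the 8 lists at an unadjusted fry p under 0.05. The voom means ran from -3.38 for skeletal muscle markers to 1.03 for interferon-gamma targets, and no list passed after adjustment.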

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

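All values in this part come from a test for a library far from the other 5 of its genotype, fixed before the data were examined. It was applied to 112 sets of 6 values (library totals, named genes on the log2(CPM + 1) scale and list scores) and singled out 4 of them, where chance alone gives about 1 in 20.

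Trim12a was at 1.54 in Arf6-null replicate 4, below the range of 2.84 to 3.50 in the other Arf6-null libraries and above every wild-type library. Trim5 was at 0.468 in wild-type replicate 3, against 0.136 to 0.201 in the other wild-type libraries. The dendritic cell score was 2.89 in Arf6-null replicate 6, against 0.696 to 1.40 in the others. The score of Wnt targets was 4.80 in Arf6-null replicate 5, against 2.99 to 3.64 in the others.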

How the results depend on the processing

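Thinning, the fit without 3 muscle-rich libraries and the muscle covariate were chosen after seeing the data. Arf6 stayed lower and past the threshold in all 22 alternatives, with log2 fold changes from -2.753 to -2.501. For the other 21 called named genes no alternative turned the direction, and 90 of 451 refits ended the call. Most of these 21 genes were named because they stayed called in each leave-one-out fit, so those refits could not end their call. The share therefore does not describe called genes in general: only 19 of the 186 were called in all 12 leave-one-out fits. Counts of higher and lower genes, 95 and 91, became 14 and 17 with Y-linked expression as a covariate and 14 and 21 without the 3 muscle-rich libraries. They became 5 and 15 with the muscle score as a covariate, 513 and 483 with limma-voom quality weights, and 641 and 718 at a threshold of 0.1. With DESeq2, run on 33373 genes without the filterByExpr step, they were 970 and 1247, so test and filter changed together. The lower count was 55 without a filter and 59 with the stricter filter, and the higher count was 36 with a 2-fold limit. Leaving out 1 library gave 13 to 388 higher and 9 to 378 lower genes. The cause was not tested, except that fewer libraries or another threshold change the power by construction. Thinning every library to the smallest total left 186 called genes, 163 of them the same, which argues against unequal depth as the source of the count. The lists past the threshold, 0 with fry, numbered 14 with camera at a preset correlation and 0 to 1 with a library left out.

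List means, on the voom scale, that changed sign were all uncalled, and the cause was not tested. Cytotoxic markers (-0.02) went to 0.84 with the stricter filter, 0.25 with the Y covariate, 0.16 with the muscle covariate and 0.065 with quality weights, and spanned -0.21 to 0.20 with a library left out. T cell markers (-0.28) went to 0.43 with the Y covariate and 0.14 with the muscle covariate, and spanned -0.60 to 0.031. Proliferation (-0.06) went to 0.11 without the muscle-rich libraries and 0.18 with the muscle covariate, and spanned -0.16 to 0.051. Pigment genes (-0.30) went to 0.023 and Wnt targets (-0.18) to 0.072 with the stricter filter, and Wnt targets to 0.022 with the muscle covariate. Dedifferentiation genes (0.05) went to -0.0065 with upper-quartile scaling and -0.066 with the muscle covariate. MHC class II spanned -0.11 to 0.55 and MAPK output -0.0099 to 0.14 with a library left out. Ckm, itself part of the muscle score, went from -5.68 to 0.11 with that score as a covariate.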

Other observations

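Tests of genomic position, of the Arf6 neighborhood, of MHC class II, and of the exchanged split (labels, stroma and sex) were chosen only after the result was seen. The muscle correlation and the thinning were added after the data were examined and before their own results were seen.

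A few other genes that rose are given here, chosen after their values were seen. Tkt, transketolase of the pentose phosphate pathway, rose from 194 ± 39.9 to 365 ± 52.4 CPM (edgeR adjusted p = 0.0213). Gpi1, glucose-6-phosphate isomerase, rose from 433 ± 78.0 to 828 ± 196 CPM (edgeR adjusted p = 0.0346). G6pc3, a glucose-6-phosphatase subunit, rose from 39.97 ± 2.696 to 54.5 ± 3.21 CPM (edgeR adjusted p = 0.0226). None of these 3 genes was called in all 12 leave-one-out fits.

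Over 2-fold separation between every wild-type and every Arf6-null library was found for 14 called genes, 5 higher and 9 lower in Arf6-null tumors. The higher genes were Trim12a, Ifi44l, H2-T22, H2-Eb1 and Trim5. The lower genes were Arf6, the overlapping Gm9887, Gm10704, Gm7224, Cda, Tmem52, Tnmd, Tmem30b and Cilp2. Gm7224 had 91 counts over the wild-type and 0 over the Arf6-null libraries. For H2-Eb1, a different share of cells with MHC class II is argued against, since the mean log2 fold change of H2-Aa, H2-Ab1 and Cd74 was -0.58 while that of H2-Eb1 was 4.96. A haplotype inherited with the Arf6 locus is argued against for the pattern as a set: with Arf6 and Gm9887 left out, 1 of 12 separated genes, Tmem30b, lay within 10 Mb of Arf6. Inherited differences at other loci stay open: 2 of the 12 lay within 1 Mb of another, against a mean of 0.224 in random sets (one-sided permutation p = 0.107), too few genes to decide. The 1 Mb window also counts H2-Eb1 and H2-T22 as apart, since they start at 34305867 and 36037128 on chromosome 17. Among all called genes 47 lay within 1 Mb of another, against a mean of 44.2 (one-sided permutation p = 0.379), while 8 of 163 tested genes at 33 to 37 Mb of chromosome 17, the MHC region, were called against 175 of 16034 elsewhere (one-sided Fisher exact p = 0.000534, region chosen after the calls were seen). The pseudogene H2-Ea-ps had 0 counts in Arf6-null replicates 1, 3, 5 and 6, 366 and 183 in replicates 2 and 4, and 52 to 918 in wild-type libraries. H2-Aa was at 283 to 835 CPM in Arf6-null replicates 1, 3, 5 and 6, and at 170 to 2187 CPM in wild type. A lack of cells with MHC class II is therefore argued against as the source of these 0 counts. Since H2-Ea-ps differed among Arf6-null tumors, genotype alone does not set it, and an inherited difference in this region is a candidate. H2-Eb1 was at 389 and 230 CPM in Arf6-null replicates 2 and 4, where H2-Aa was at 1117 and 752 CPM. In replicates 1, 3, 5 and 6 H2-Eb1 was at 199, 392, 423 and 616 CPM with H2-Aa at 283, 560, 529 and 835 CPM. Relative to H2-Aa, H2-Eb1 was thus lower in the Arf6-null replicates with H2-Ea-ps counts, so genotype alone does not set this relation either. An effect of Arf6 loss on the separated genes remains open and was not told apart from inherited differences. Strain is not given in the labels.

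Called genes were also frequent near Arf6, a set that apart from Tmem30b differs from the separated genes: 6 of 102 tested genes within 10 Mb, Arf6 and overlapping genes left out, were called against 177 of 16095 elsewhere (one-sided Fisher exact p = 0.00105). They were Nin, Fntb, Tmem30b, Vcpkmt, Plekhg3 and Gm15283. A haplotype inherited with the locus is a candidate explanation, and a local effect of the deletion was not tested.

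Of 100 splits of the 12 libraries into 6 and 6, the real one included, 2 gave as many genes in one direction, for the 95 higher as for the 91 lower genes. A random division of the samples is thus argued against as the source of the count. A rank among random splits cannot exclude that the genotypes lie by chance along another structure of the samples. The other split, with wild-type replicate 2 and Arf6-null replicate 6 exchanged, called 761 and 610 genes, several times the real count, which points to a structure of the samples beside the genotype. The next highest total was 3. Swapped labels are argued against: Arf6 was at 147 CPM in wild-type replicate 2 and at 20.7 CPM in Arf6-null replicate 6. Sex stays open: Xist exceeded 100 CPM in 4 of the 6 libraries of one side and in 0 of the 6 on the side of wild-type replicate 2, so sex follows this split in part. A different share of stromal cells may contribute: 4 of the 5 stromal lists scored lower on the side of wild-type replicate 2 at an exact permutation p under 0.05. The endothelial list did not reach it, so the test leaves it open. Differences were -3.34 for muscle, -1.02 for fibroblast, -0.782 for Schwann, -1.51 for adipocyte and -0.508 for endothelial lists. Between genotypes they were of similar size, at -3.41, -0.904, -0.640, -1.30 and -0.705 in the same order. On that side the hypoxia and glycolysis score was higher by 1.24 (exact permutation p = 0.00216, the smallest possible). Scores also differed by 0.278 for other ARF GTPases and by -0.312 for ARF6 exchange factors and GTPase-activating proteins (exact permutation p = 0.00216 and 0.00433), against 0.224 and -0.289 between genotypes. Dendritic cell markers differed by -1.54 (exact permutation p = 0.00216), against -1.02 between genotypes. These 4 lists, hypoxia and glycolysis included, passed the exact permutation test after adjustment in this split (adjusted p of at most 0.039), while none did between genotypes. The split matches the sign of the first principal component: positive in wild-type replicate 2 and Arf6-null replicates 1 to 5, negative elsewhere. Picked from these same libraries for its count, it has p-values that cannot be set against those between genotypes. The split keeps 5 of 6 libraries per side, so shared calls are built in. It shares 62 of the 186 genotype calls, where independent lists would share 15.7, and it was picked for its count.

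Muscle tissue in some wild-type samples was tested as the source of the lower genes. Outside the list itself, the 90 lower genes had a median within-group correlation with the muscle score of -0.065. That lay below the 95th percentile of random sets (0.08), which argues against muscle for the called lower genes as a set. A median cannot show a subset: for 14 of the 90 the correlation exceeded 0.5, up to 0.894 for Cmya5. The share above 0.5 in random sets was not computed. Spread from muscle within wild type also makes a call less likely, so the test covers called genes only. The fits without the muscle-rich libraries or with the score as a covariate called 35 and 20 genes. Loss of libraries or of degrees of freedom lowers power as well, so these counts do not tell how far muscle enters single genes. The effect of genotype on the surrounding tissue stays open as well.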
